A study of Homo sapiens with 4 samples.

How the data were processed

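RNA from 4 established human melanoma cell lines (RPMI-7951, A375, SK-MEL-5 and SK-MEL-1) was measured on Agilent two-colour gene expression arrays, 1 array per line. Per the labels, the Cy5 channel of each array held RNA of cells treated with interferon-beta at 1000 IU/ml for 48 h, and the Cy3 channel held RNA of the untreated cells of the same line. Per the labels, cells grew in medium with 10% fetal bovine serum and RNA was extracted with RNeasy columns. The lines are numbered as replicates in the order given here. All 4 arrays were on 1 slide and read in 1 scan, so there was no batch to compare. No array had the dyes swapped, and no line had a second array. A primary melanocyte culture mentioned in the series text was not analysed here.

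Per the submitters' processing notes and the file headers, the authors scanned the arrays and read them with Agilent Feature Extraction 10.7.3.1 under a two-colour gene expression protocol, with probes placed on hg19. Per the file headers, the deposited mean signals and local median backgrounds are raw pixel intensity values of each channel. The deposited processed signals are intensity values after background subtraction, spatial and multiplicative detrending and linear plus LOWESS dye normalization, with surrogate values for dim spots. The deposited ratio of each spot is the log10 of processed Cy5 over processed Cy3. The deposited error of that ratio is a score from Agilent's error model, a technical standard error on the log10 scale. Other deposited columns hold flags of 0 or 1 per spot for signals well above background, saturation and non-uniform spots. The authors' series matrix gives log10 ratios of Cy5 over Cy3, positive where the treated cells were higher. Checked spot by spot, these equalled the arrays' own ratios after rounding in 100% of spots on each array, with a correlation of 0.999999, and each column had a median of 0. They were not centred further. Versions of any labelling or hybridisation kit are not given in the sources used here.

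Each array held 62976 spots, of which 1319 were control spots and 2940 external-control spots, and these did not enter the gene tests. Of 50599 probes, 28174 were given a current gene symbol by RefSeq accession and 3238 by name or synonym, from a RefSeq table on GRCh38 used for names alone. The other 19187 kept the name in the file. This gave 36400 genes or transcripts. Spots well above background made up 36.4 to 47.2% of the Cy3 channel and 45.2 to 53.7% of the Cy5 channel. No spot was saturated. The median SD of log2 ratios over repeated spots of a probe was 0.08 to 0.11 between arrays. The number of arrays limits the precision, and p-values measure the spread between these lines.

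The main values were recomputed from raw signals with limma 3.58.1 in R 4.3.3. Local background was corrected by normexp with an offset of 50, log2 ratios of Cy5 over Cy3 were normalized within each array by loess with control spots at weight 0, and spots marked as non-uniform or as population outliers were dropped. Spots of a probe were averaged, and the brightest probe stood for each gene. A gene was tested if its probe was well above background in either channel on at least 2 of the 4 arrays, which left 18220 genes (14067 with a current symbol). An intercept was fitted to the 4 log2 ratios and tested against 0 with limma's moderated statistic, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Within a line there was no replicate, so genes were counted there at 2-fold (1 on the log2 scale) without a test, and Agilent's technical error is printed beside single values. A fold is written "at least" where the untreated channel was not well above background on any array. That bound takes as untreated signal the higher of the spot's own signal and the lowest signal called well above background in that channel of that array, and it is open to dye bias, since no dyes were swapped.

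Lists of genes were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. The 21 lists cover core interferon-stimulated genes, the interferon receptor with JAK-STAT and feedback genes, nucleic acid sensing, virus restriction factors, MHC class I with antigen processing, MHC class II, interferon-gamma-associated genes, chemokines and cytokines, immune checkpoint and NK-cell ligands, death receptors and apoptosis, melanocyte lineage and pigmentation, melanoma dedifferentiation and invasion, cell proliferation, p53 targets and cell cycle inhibitors, MAPK pathway output, unfolded protein and stress response, NF-kappaB feedback and targets, cholesterol synthesis and uptake, glycolysis and hypoxia, reference genes, and markers of other cell types. Lists share some members, such as USP18. Each list was tested against the other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. The fry test asked whether a list moved in one direction on balance, and its mixed form whether members moved in either direction. Neither compares a list with other genes. On each array a list's median was placed among 10000 random lists of equal size matched on brightness over 20 bins.

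Named genes were the 15 largest rises and 10 largest falls among genes past the test with the same sign in every line, 16 genes fixed by name, up to 4 members per list with the largest mean change, the 5 largest rises and 3 largest falls in each line, and the 5 genes that most exceeded and the 3 that lay furthest below the nearest other line. Probes without a gene symbol were counted but not named, and the values of some named genes are not reported here. A named gene or list was marked for a closer look where a line's gap to the nearest other line, divided by the range of all lines, was above Dixon's limit of 0.829, or where lines passed 2-fold in opposite directions.

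The gene-level fit was tested on simulated log ratios in 5 sets of 18220 genes with 200 changed, with SDs drawn from the fit's own prior. It recovered 98.6% of genes changed by 2-fold and 100% of genes changed by 4-fold, and 5.16% of its calls were on unchanged genes. These simulated ratios held no dye effects shared by the arrays and no correlation between genes, and skipped background correction and loess. The shares therefore do not give the error rate of the real calls. The alternatives were Agilent's processed signals, the series matrix values, no background subtraction, an offset of 16, median centring in place of loess, no filter on dim probes, a filter asking for both channels on all arrays, the median over a gene's probes, all probes tested, saturated spots left out, scale normalization between arrays, a trended and robust prior, limma treat at 1.5-fold, thresholds of 1.5-fold and 3-fold, the other set tests, the mean over a list, and each line left out. Untreated channels were compared between lines after Aquantile normalization, with quantile normalization and scaling to the upper quartile as alternatives. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. With Agilent's processed signals and with the series matrix values, the count of genes at least 2-fold higher in all lines was 107 each time, and the closing section gives it rounded.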

Results

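The arrays compared each of 4 established human melanoma lines with itself, with and without interferon-beta (IFN-β), a type I interferon that cells release on virus infection. RPMI-7951, A375, SK-MEL-5 and SK-MEL-1 each gave 1 array, with treated cells (1000 IU/ml for 48 h) in Cy5 and untreated cells in Cy3, so positive log2 ratios mean higher in treated cells. The dyes were not swapped, so a probe's dye effect stays in a mean over lines and cancels between lines. Spots well above background in the untreated channel made up 39.5% in RPMI-7951, 37.5% in A375, 36.4% in SK-MEL-5 and 47.2% in SK-MEL-1. In the treated channel these shares were 45.2%, 48.1%, 45.4% and 53.7%. The number of arrays limits the precision. No line had a replicate, so no test was made within a line or between lines.

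The first question was which genes changed with IFN-β across the 4 lines. The largest rises among named genes were antiviral genes. ISG15, a ubiquitin-like protein that is attached to other proteins, rose by 5.25 ± 0.27 on the log2 scale (SD between lines, n = 4), with adjusted p = 5.9e-08 by limma. IFIT1, which binds viral RNA lacking a host cap, rose by 4.89 ± 0.26 (adjusted p = 6.4e-08, n = 4, limma). IFI6 and IFI27, membrane proteins known as interferon-induced genes, rose by 5.18 ± 0.46 and 4.56 ± 0.18. BST2, which tethers budding virus at the cell surface, rose by 4.47 ± 0.79, with an untreated signal well above background on 3 arrays. The means of the BST2 probes spanned 0.78. MX1, a GTPase that blocks virus replication, rose by 3.97 ± 2.04 (adjusted p = 0.012, limma). RSAD2, the antiviral enzyme viperin, was at least 13.0-fold higher (adjusted p = 0.015, limma), its untreated signal not being well above background on any array. On hg19, the ISG15 probe lies on chromosome 1 from 949567 to 949626, the IFIT1 probe on chromosome 10 from 91163438 to 91163497 and the MX1 probe on chromosome 21 from 42831014 to 42831073.

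The other named rises at the top were IRF7, CMPK2, DHX58, OASL, IFITM3, IFIT3, IFITM1 and IFITM2, with means from 3.27 for IFITM2 to 3.86 for IRF7, a transcription factor of interferon genes. CMPK2 and IFIT3 had an untreated signal well above background on 3 arrays and OASL on 2. Another CMPK2 probe had untreated signal well above background on no array, so its ratio is at best a lower bound. The means of the CMPK2 probes spanned 3.61. A low lower bound does not contradict the main probe's 3.78, but does not repeat it either. Another IFITM1 probe read 5.13 where the main probe read 3.29. Probes of the IFITM genes can share signal between these close relatives, so which member a ratio belongs to is uncertain. Without A375, MX1 (mean 3.65, adjusted p = 0.0941), RSAD2 (adjusted p = 0.095) and OASL (mean 3.20, adjusted p = 0.0812) no longer passed limma's threshold. OASL did not pass it without SK-MEL-5 either (mean 3.57, adjusted p = 0.0681). With a trended and robust prior in limma, which leaves means and SDs as they are, MX1, RSAD2, CMPK2, OASL and IFIT3 did not pass.

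Falls were smaller. DANCR, a long noncoding RNA, fell by 1.70 ± 0.82 (SD, n = 4, adjusted p = 0.012, limma). NT5DC2, named for its 5'-nucleotidase domain, fell 2.82-fold (SD 0.47 on the log2 scale, adjusted p = 0.0018, limma), and PRKCA, a protein kinase C, fell by 1.26 ± 0.58 (adjusted p = 0.012, limma). CERK, which makes ceramide-1-phosphate, fell by 1.09 ± 0.26 (adjusted p = 0.0012, limma). RFLNB, ACACA, PTPN14, CMTM4, SLC26A2 and HNRNPA0 fell by 0.91 to 1.05, RFLNB with a treated signal well above background on 3 arrays. Other ACACA and PTPN14 probes read closer to 0, at -0.15 for ACACA and at -0.39 and -0.75 for PTPN14. Of these 10 falls, CERK kept its call with Agilent's processed signals (mean -1.54, adjusted p = 0.031, limma), and the other 9 lost it at means further from 0, from -1.24 for ACACA to -2.18 for RFLNB. The SD between lines was wider for each of these 9, at 0.52 for NT5DC2 (0.47 in the main values) and 1.57 for RFLNB (0.38 in the main values). PRKCA lost its call without A375 (mean -1.11, adjusted p = 0.083) and without SK-MEL-5 (mean -1.37, adjusted p = 0.055). RFLNB lost it without SK-MEL-5 (adjusted p = 0.0504), and CMTM4 without A375 or SK-MEL-5 (0.0728 and 0.0548). With RPMI-7951, A375 or SK-MEL-5 left out, ACACA had an adjusted p of 0.0579, 0.176 and 0.113, SLC26A2 of 0.0709, 0.095 and 0.114, and PTPN14 of 0.0973, 0.215 and 0.0718. The SLC26A2 mean was -0.95, -0.59 and -1.01 in the same order. PTPN14 lost its call without SK-MEL-1 as well (adjusted p = 0.051).

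Over all 18220 genes tested, 587 rose and 339 fell at an adjusted p under 0.05 in limma, so 63.4% of the calls were rises. With a mean change of at least 2-fold there were 124 rises and 8 falls. All but 1 of the rises and all of the falls had the same sign in every line. The counts depended on each line, with 309 rises and 143 falls without RPMI-7951, 105 and 11 without A375, 172 and 25 without SK-MEL-5, and 324 and 238 without SK-MEL-1. With Agilent's processed signals 98.1% of the calls were rises (102 rises, 2 falls), and 32 of 59 named genes that passed the test lost their call, among them MX1, RSAD2, IRF9, CD274, IFIH1, RIGI, TNFSF13B, DDIT3, CHAC1, RELB, KIF11, WNT5A and EEF1A1. Most of these means were further from 0 there, with IRF9 at 3.46 (SD 1.19, against 0.57), IFIH1 at 3.90 (SD 1.49, against 0.65), CD274 at 1.34 (SD 1.30, against 0.11) and MX1 at 4.25 (SD 1.69, against 2.04). RELB stayed at 0.84. With median centring in place of loess the median of all genes was 0.41, a shift of 0.37, and 99.7% of the calls were rises (10971 rises, 28 falls, of which 16 were also falls with loess), so falls here are relative to the loess curve of each array. With that centring 8 of the 59 named genes lost their call (ACACA, SLC26A2, WNT5A, KIF11, BUB1B, CYP51A1, EEF1A1 and TFRC). TGFBI, a fall with loess, was instead called as a rise there (mean 0.37, adjusted p = 0.016, limma), at a value below the median of all genes. The trended and robust prior ended 17 named calls, those of MX1, RSAD2, CMPK2, OASL, IFIT3, DANCR, ACACA, PTPN14, SLC26A2, RIGI, SECTM1, TNFSF13B, CASP1, BUB1B, DDIT3, CHAC1 and RELB. The median over a gene's probes ended 16, among them ACACA, PTPN14, SLC26A2, CD274, HLA-DMA, SECTM1, TNFSF13B, WNT5A, BUB1B, RELB, CYP51A1, EEF1A1 and TFRC. Keeping dim probes ended 7 (PTPN14, SLC26A2, RIGI, SECTM1, CASP1, RELB and CYP51A1), and an offset of 16 ended 5 (TGFBI, BUB1B, RELB, CYP51A1 and TFRC).

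**Figure D1:**
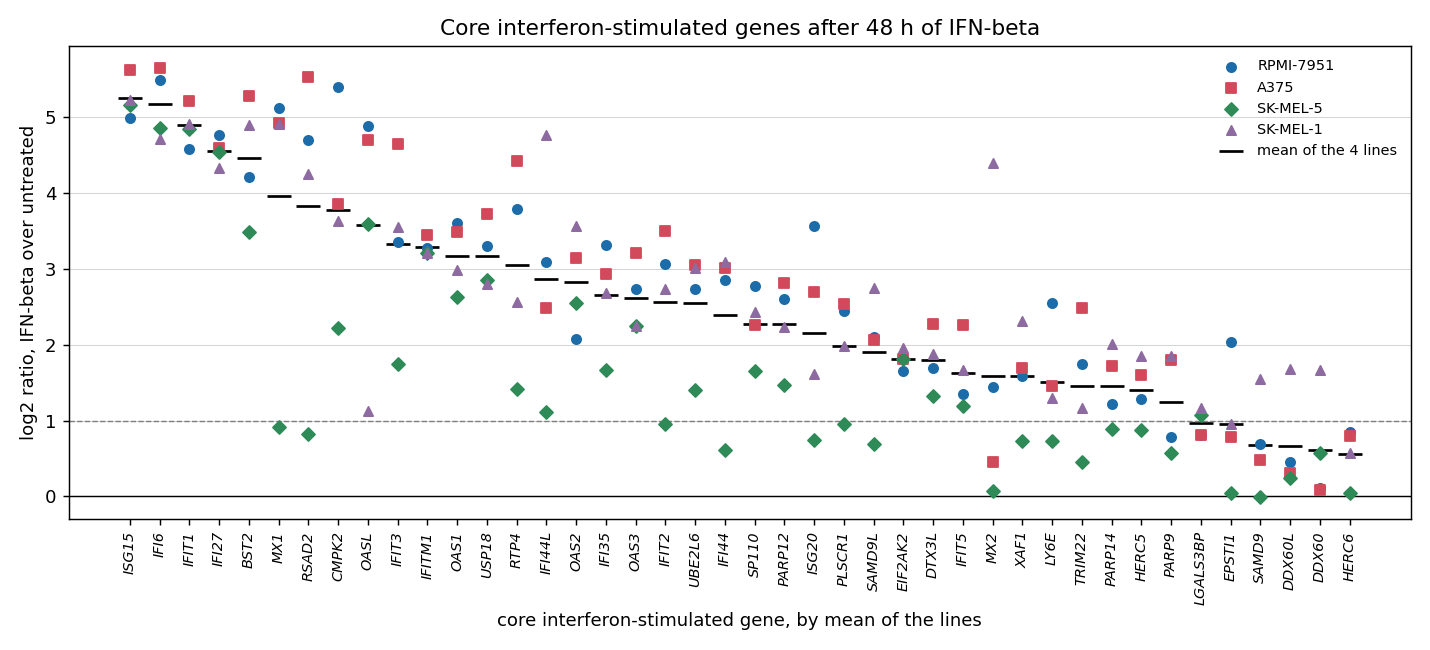
Log2 ratio of IFN-β-treated over untreated cells for each core interferon-stimulated gene, with 1 marker per cell line. ISG15 sits between 4.99 and 5.62 in every line, while MX1 is at 0.91 in SK-MEL-5 and between 4.91 and 5.12 in the other lines.

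The second question was which groups of genes moved. Of 42 core interferon-stimulated genes, 37 rose and none fell over all genes, and 42 rose adjusted over the list alone, with a list median of 2.34 (camera adjusted p = 9.03e-46, adjusted p = 0.274 with an estimated correlation). The members that did not pass over all genes were MX2, DDX60L, DDX60, SAMD9 and EPSTI1, selected for naming after their values were seen. In the interferon receptor and JAK-STAT list, 9 of 17 measured genes rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 1.86e-05, adjusted p = 0.274 with an estimated correlation). IRF9, a DNA-binding factor of type I interferon signalling, rose by 2.57 ± 0.57 (SD, n = 4) and was well above background untreated on 3 arrays. USP18, which limits signalling at the interferon receptor, rose by 3.17 ± 0.43. The member that fell was PTPN11, the phosphatase SHP2, which fell by 0.62 and was named after its value was seen.

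Sensors of viral nucleic acid rose in 10 of 16 genes (13 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 5.66e-10, adjusted p = 0.274 with an estimated correlation). DHX58 rose by 3.65 ± 0.91 and IFIH1, the RNA sensor MDA5, by 2.31 ± 0.65, the latter well above background untreated on 2 arrays. EIF2AK2, the RNA-activated kinase PKR, rose by 1.81 ± 0.12. RIGI, another RNA sensor, rose by 1.49 ± 1.12 (adjusted p = 0.044, limma), was well above background untreated on 3 arrays and lost its call without RPMI-7951, A375 or SK-MEL-1 (adjusted p = 0.0696, 0.136 and 0.0981). In SK-MEL-5 its main probe was at least 1.13-fold higher, its untreated signal not being well above background there, and another probe read 1.51, also without untreated signal well above background. Of 19 virus restriction factors, 10 rose (12 adjusted over the list alone), with a median of 0.68 (camera adjusted p = 1.07e-09, adjusted p = 0.274 with an estimated correlation). Among them ADAR, which edits double-stranded RNA, rose by 1.31 ± 0.29 and TRIM14, an adaptor of antiviral signalling, by 1.71 ± 0.46. The means of the TRIM14 probes spanned 0.94, so the size of its rise depends on the probe.

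Antigen presentation genes of MHC class I rose in 14 of 22 members (18 rose and 1 fell adjusted over the list alone), with a median of 1.01 (camera adjusted p = 1.44e-17, adjusted p = 0.274 with an estimated correlation). TAP1, a peptide transporter, rose by 2.64 ± 0.43 and B2M, the light chain of class I molecules, by 2.29 ± 0.37 (SD, n = 4). HLA-C and HLA-B read 2.54 ± 0.22 and 2.42 ± 0.18, and both passed, but HLA probes can share signal between genes and are uncertain. Of 11 MHC class II genes, HLA-DMA alone rose over all genes, by 0.44 ± 0.17, and 7 rose adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.000967, adjusted p = 0.441 with an estimated correlation). HLA-DMA lost its call without RPMI-7951, A375 or SK-MEL-5 (adjusted p = 0.0636, 0.176 and 0.106). Interferon-gamma-associated genes rose in 11 of 19 members (15 adjusted over the list alone), with a median of 0.76 (camera adjusted p = 1.08e-10, adjusted p = 0.383 with an estimated correlation). BATF2, a transcription factor, rose 8.55-fold (SD 0.83 on the log2 scale, untreated signal well above background on 3 arrays) and WARS1, a tRNA synthetase, by 1.68 ± 0.63. APOL6 rose by 1.73 ± 0.28. Another of its probes read 0.48, a lower bound, with untreated signal well above background on no array and treated signal on 4. SECTM1, a secreted and membrane protein, rose by 1.46 ± 1.06 (well above background on 3 arrays) and lost its call without RPMI-7951, A375 or SK-MEL-1 (adjusted p = 0.0807, 0.188 and 0.0857).

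Of 18 chemokines and cytokines, 2 rose over all genes and 9 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 1.20e-05, adjusted p = 0.441 with an estimated correlation). TNFSF13B, the B-cell survival factor BAFF, rose by 1.11 ± 0.70 (adjusted p = 0.029, limma), was well above background untreated on 1 array and lost its call without A375 or SK-MEL-1 (adjusted p = 0.173 and 0.0518). CXCL10, a T-cell attractant, was not past the test (adjusted p = 0.30, limma), with untreated signal well above background on no array and treated signal on 2. In the list of immune checkpoint and NK-cell ligands 4 of 17 rose (8 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.000101, adjusted p = 0.408 with an estimated correlation). HLA-E, a ligand of NK-cell receptors, rose by 1.82 ± 0.29. CD274, the checkpoint ligand PD-L1, rose by 0.41 ± 0.11 (adjusted p = 0.029, limma), with untreated signal well above background on 1 array, and it lost its call with any 1 line left out (adjusted p = 0.073 without RPMI-7951, 0.167 without A375, 0.0628 without SK-MEL-5 and 0.0813 without SK-MEL-1). Death receptor and apoptosis genes rose in 6 of 34 members (11 rose and 1 fell adjusted over the list alone), with a median of 0.23 (camera adjusted p = 2.69e-05, adjusted p = 0.394 with an estimated correlation). XAF1, an antagonist of an apoptosis inhibitor, was at least 2.69-fold higher (adjusted p = 0.0063, limma) and lost its call without A375 (adjusted p = 0.0578). TNFSF10, the death ligand TRAIL, was not past the test (adjusted p = 0.14, limma), with untreated signal well above background on no array and treated signal on 3.

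NF-κB targets rose in 2 of 15 members, RELB and NFKB2, both subunits of NF-κB itself (5 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 2.69e-05, adjusted p = 0.451 with an estimated correlation). RELB rose by 0.84 ± 0.63 (SD, n = 4) and lost its call without RPMI-7951, A375 or SK-MEL-5 (adjusted p = 0.0615, 0.187 and 0.143). The RELB mean was 0.56, 0.89 and 0.85 in the same order. NFKB2 rose by 0.46 and was named after its value was seen. In the stress response list 2 of 20 genes rose and 1 fell (6 and 2 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.186, adjusted p = 0.526 with an estimated correlation). DDIT3, the stress factor CHOP, rose by 1.47 ± 0.75 and CHAC1, which degrades glutathione, by 1.30 ± 0.79, where another CHAC1 probe, with untreated signal well above background on 2 arrays, read 0.61. Without A375 neither passed (adjusted p = 0.092 for DDIT3 and 0.112 for CHAC1, limma), and CHAC1 did not pass without SK-MEL-5 or SK-MEL-1 (adjusted p = 0.056 and 0.060). The member that fell was HSP90B1, an endoplasmic reticulum chaperone, which fell by 0.47 and was named after its value was seen.

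Proliferation genes had a median of -0.15 over 30 members, of which 2 fell and none rose (2 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.000101, adjusted p = 0.488 with an estimated correlation). By line their median was -0.20 in RPMI-7951, -0.34 in A375 and -0.083 in SK-MEL-1, but 0.15 in SK-MEL-5, where 24 of the 30 had their highest ratio. KIF11, a spindle motor, fell by 0.45 ± 0.17 and BUB1B, a spindle checkpoint kinase, fell by 0.40 ± 0.19. The dedifferentiation list, of genes of invasive melanoma, had a median of -0.11 over 22 members, of which 2 fell (3 adjusted over the list alone; camera adjusted p = 0.00573, adjusted p = 0.458 with an estimated correlation). This median was below 0 in RPMI-7951 and A375 alone (-0.32 and -0.27, against 0.029 in SK-MEL-5 and 0.013 in SK-MEL-1), and it turned to 0.031 among genes well above background in both channels on all arrays. WNT5A, a secreted Wnt ligand, fell by 0.46 ± 0.26 (well above background on 3 arrays) and TGFBI, a matrix protein, fell by 0.40 ± 0.11. Cholesterol genes had a median of -0.086 over 20 members, of which CYP51A1, a sterol demethylase, fell by 0.50 ± 0.30 (1 adjusted over the list alone; camera adjusted p = 0.0406, adjusted p = 0.573 with an estimated correlation). Without RPMI-7951 the cholesterol median was 0.049. None of these 5 falls held with every line left out in turn. KIF11 lost its call without RPMI-7951, A375 or SK-MEL-1 (adjusted p = 0.0739, 0.167 and 0.0863) and CYP51A1 without RPMI-7951, A375 or SK-MEL-5 (0.107, 0.217 and 0.129). BUB1B, WNT5A and TGFBI lost theirs with any 1 line left out, at adjusted p of 0.113, 0.112 and 0.0798 without RPMI-7951, 0.219, 0.216 and 0.101 without A375, 0.0736, 0.0519 and 0.0954 without SK-MEL-5, and 0.0931, 0.103 and 0.0945 without SK-MEL-1. With median centring BUB1B, TGFBI and CYP51A1 read 0.19, 0.37 and 0.11 and the medians of these 3 lists turned positive (0.53 for proliferation, 0.27 for dedifferentiation and 0.43 for cholesterol), where the median of all genes was 0.41.

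Melanocyte lineage genes, which serve pigment production, had a median of 0.0020 over 22 members and a mean of 0.019 with a downward camera test (camera adjusted p = 0.503, adjusted p = 0.749 with an estimated correlation), and none passed over all genes (1 rose and 2 fell adjusted over the list alone). The line medians differed in sign, at 0.14 in A375 (percentile 92.1 of random lists) and -0.21 in SK-MEL-5 (percentile 0.02, 13 of 22 members lowest there). RPMI-7951 and SK-MEL-1 read -0.060 and 0.014, at percentiles 14.8 and 31.5. With median centring the SK-MEL-5 median was 0.36, where the median of all genes tested in that line was 0.37. Fry's mixed test, which takes changes in both directions, called this list (adjusted p = 0.0195). MITF, the lineage's main transcription factor, read 0.14 ± 0.77 (adjusted p = 0.76, limma), and PMEL, a melanosome protein, read 0.20 ± 0.39 (adjusted p = 0.39, limma) with untreated signal well above background on 3 arrays. Of the p53 targets none of 19 passed (4 rose adjusted over the list alone), with a median of 0.086 (camera adjusted p = 0.114, adjusted p = 0.570 with an estimated correlation), and CDKN1A, the cell cycle inhibitor p21, read 0.39 ± 0.38 (adjusted p = 0.13, limma) with untreated signal well above background on 3 arrays. MKI67, a marker of cycling cells, read -0.23 ± 0.39 (adjusted p = 0.33, limma), and 0.24 with median centring. MAPK output genes had a median of 0.14 over 20 members and none passed, over all genes or adjusted over the list alone (camera adjusted p = 0.119, adjusted p = 0.573 with an estimated correlation). Glycolysis and hypoxia genes had a median of 0.033, a mean of -0.042 and a downward camera test over 18 members, none of which passed either way (camera adjusted p = 0.176, adjusted p = 0.718 with an estimated correlation). Markers of fibroblasts, leukocytes, keratinocytes and endothelium, of which 9 were measured, had a median of 0.065 and none passed either way (camera adjusted p = 0.666, adjusted p = 0.718 with an estimated correlation).

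Of 18 reference genes, often taken as stable, 1 rose and 2 fell (1 and 6 adjusted over the list alone), with a median of -0.043 (camera adjusted p = 0.0755, adjusted p = 0.441 with an estimated correlation). EEF1A1, a translation elongation factor, fell by 0.63 ± 0.32 and TFRC, the transferrin receptor, fell by 0.56 ± 0.33 (SD, n = 4), while with median centring they read 0.20 and 0.14, below that setting's median of all genes. EEF1A1 lost its call without A375 or SK-MEL-5 (adjusted p = 0.137 and 0.0688) and TFRC without RPMI-7951, A375 or SK-MEL-5 (0.0876, 0.198 and 0.109). In all, camera called 11 lists higher and 3 lower, and none with an estimated correlation. The fry test called 5 higher and none lower. Its mixed form, which gives no direction, called 10 lists whose sign in the directional fry test was upward and 2 whose sign was downward. Among the 10 was the melanocyte list, with a directional fry p of 0.98.

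**Figure D2:**
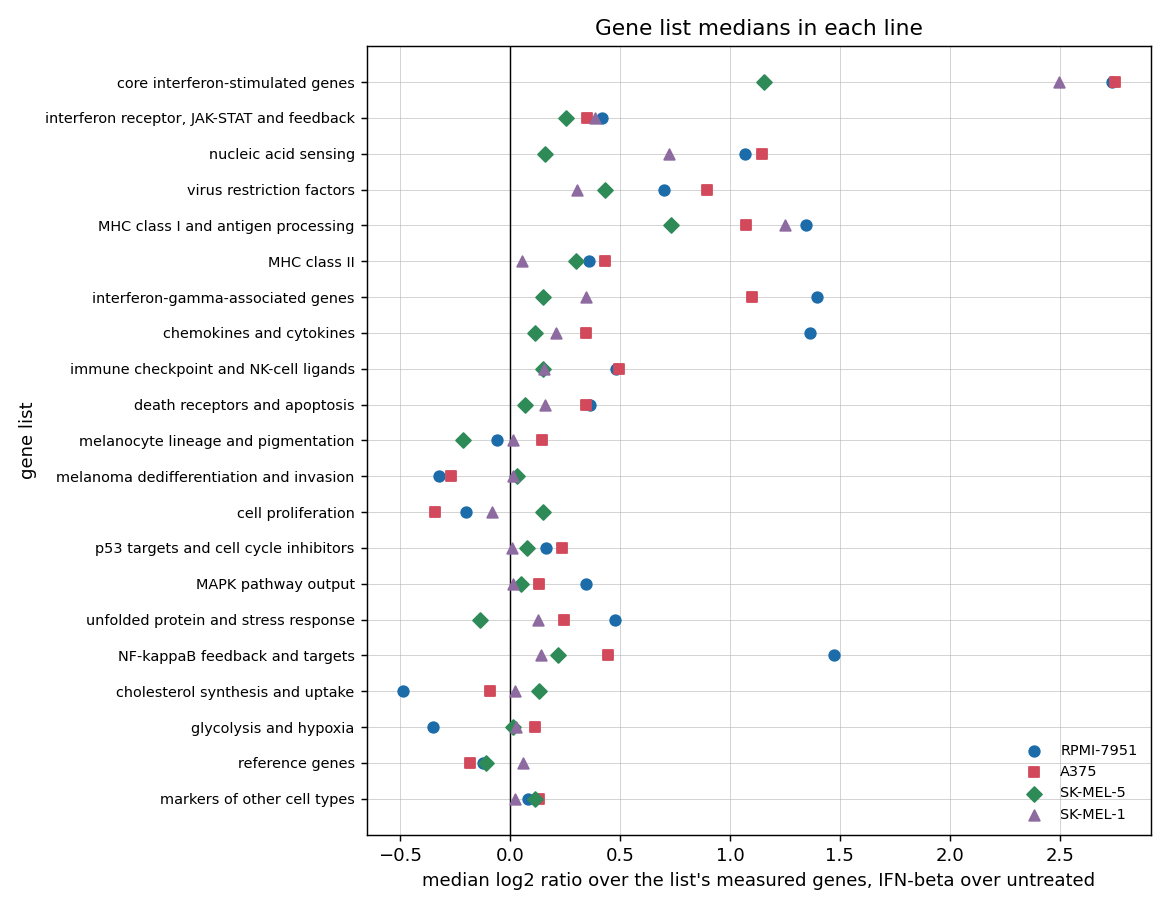
Median log2 ratio of treated over untreated cells (horizontal axis) for each fixed gene list (vertical axis), with 1 marker per cell line. The core interferon list lies between 1.16 in SK-MEL-5 and 2.75 in A375, and the NF-κB list lies at 1.47 in RPMI-7951 and between 0.14 and 0.45 in the other lines.

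The next question was how each line responded on its own, with values given beside Agilent's technical standard error. In RPMI-7951, 331 genes were at least 2-fold higher and 88 at least 2-fold lower, the former with 36 of 42 measured core interferon genes. Its largest values above the other lines were CXCL1, a neutrophil attractant, at 4.16 ± 0.48, EGR1, an immediate-early transcription factor, at 3.75 ± 0.51, LGALS9, a galectin, at 2.68 ± 0.39 and SLC3A2, an amino acid transporter chain, at 2.28 ± 0.29. IL6, an inflammatory cytokine, read 4.28 ± 0.46. The NF-κB list had a median of 1.47 and the chemokine list 1.36 in this line, both above all of 10000 random lists. The cholesterol, glycolysis and dedifferentiation lists had medians of -0.49, -0.35 and -0.32 there, each below all of 10000 random lists. With median centring these lists read -0.076, 0.30 and 0.32, where the median of all genes tested in this line was 0.35. Of their members, 16 of 20 cholesterol genes, 15 of 18 glycolysis genes and 10 of 22 dedifferentiation genes had their lowest ratio in RPMI-7951. Its lower values included AHNAK, a large scaffold protein, at -2.24 ± 0.30 (its other probes read 0.17 and -1.41), NT5DC2 at -2.04 ± 0.28 and PRKCA at -1.77 ± 0.29. SNORA6, a small nucleolar RNA, at -1.41 ± 0.26 and MMP9, a matrix protease, at -1.01 ± 0.24 were among the genes below the other lines. The counts were 1214 and 661 with Agilent's processed signals.

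In A375, 274 genes were at least 2-fold higher, with 35 of 41 measured core interferon genes, and 91 at least 2-fold lower. Those furthest above the other lines included SNAR-B2, a small noncoding RNA, at 2.93 ± 0.33, RIGI at 2.92 ± 0.42, DHRS2, a dehydrogenase, at 2.71 ± 0.36, and SPON2, a matrix protein, at 1.84 ± 0.27. SPP1, the secreted protein osteopontin, was at least 3.51-fold higher, with untreated signal not well above background. The proliferation and dedifferentiation lists had medians of -0.34 and -0.27 in A375, each below all of 10000 random lists. With median centring these lists read 0.48 and 0.53, where the median of all genes tested in A375 was 0.53. DANCR read -2.67 ± 0.36, MDFIC -2.21 ± 0.36 (another MDFIC probe was not well above background there in either channel), AHNAK -1.73 ± 0.27 (its other probes read -0.13 and -1.01) and IGFBP2, a binding protein of insulin-like growth factors, -1.28 ± 0.24. MITF read 1.25 ± 0.24 with the main probe and 0.53 and 0.38 with its other probes. Agilent's processed signals gave counts of 1643 and 477.

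In SK-MEL-5, 94 genes were at least 2-fold higher, with 23 of 38 measured core interferon genes, and 48 at least 2-fold lower. ISG15 read 5.16 ± 0.54, IFI6 4.86 ± 0.54, IFIT1 4.85 ± 0.57 and IFI27 4.54 ± 0.48, while MX1 read 0.91 ± 0.29. IFI44, an interferon-induced protein, was at least 1.52-fold higher and RSAD2 at least 1.53-fold, neither with untreated signal well above background there. Values above those of the other lines included CEND1, a neuronal protein, at 1.66 ± 0.28, and the metallothionein family members MT1L at 1.26 ± 0.23 and MT1E at 1.22 ± 0.24, whose probes may share signal. Another MT1E probe was not well above background in either channel in this line, so the MT1E value rests on 1 probe. CMTM4 read -1.39 ± 0.26, ZNF550, a zinc finger gene, -1.31 ± 0.30 and CERK -1.29. Agilent's processed signals gave 1135 and 287.

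In SK-MEL-1, 101 genes were at least 2-fold higher, with 40 of 42 measured core interferon genes, and 5 at least 2-fold lower. ISG15 read 5.22 ± 0.54 and MX1 4.91 ± 0.52. MX2, a relative of MX1 that restricts HIV, was at least 18.7-fold higher, where another MX2 probe read 0.47. DDX60L, an antiviral helicase relative, read 1.68 ± 0.33 and REC8, a cohesin subunit, was at least 2.41-fold higher. Each had untreated signal well above background on 1 array, so how they compare with the other lines stays open. OASL was at least 1.99-fold higher, its untreated signal not being well above background there. NPIPB15 at 0.52 ± 0.21 (another probe read 0.37) and TREX1, a DNA-degrading enzyme, at 0.38 ± 0.21 lay below the other lines. DANCR read -1.71 ± 0.26 and NT5DC2 -1.17 ± 0.23. With Agilent's processed signals the counts were 727 and 86, and the counts of all lines moved with median centring, to 1436 and 10 in RPMI-7951, 3158 and 7 in A375, 1440 and 0 in SK-MEL-5 and 418 and 1 in SK-MEL-1.

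The last question was how far the lines shared their response. In all 4 lines, 57 genes were at least 2-fold higher, 22 of them core interferon genes, and 1 was at least 2-fold lower, NT5DC2. Shuffling genes within lines gave a mean of 0 and a highest of 0 shared genes over 1000 permutations, in either direction. The shuffle treats the lines as independent lists and breaks the dye effects of probes that all arrays share, so it gives no value for unchanged lines. A further 231 genes were at least 2-fold higher in 1 line alone, and 154 lower. Of those higher in 1 line alone, 131 were in RPMI-7951, 80 in A375, 13 in SK-MEL-5 and 7 in SK-MEL-1, counts that rest on a threshold and not on a test between lines. Without SK-MEL-5 the remaining lines shared 86 genes at least 2-fold higher. Core interferon genes had medians of 2.74 in RPMI-7951, 2.75 in A375, 1.16 in SK-MEL-5 and 2.50 in SK-MEL-1, each above all of 10000 random lists. In SK-MEL-5 several of these ratios are lower bounds, and 38 of the 42 core genes in the median were well above background there in either channel. Of 22 core genes well above background in both channels on all arrays, 10 lay in SK-MEL-5 within 0.5 of the mean of the other lines and 8 lay below it by more than 1. Across genes, Pearson's r between lines ran from 0.43 (RPMI-7951 with SK-MEL-5) to 0.72 (RPMI-7951 with A375) over 6 pairs, and from 0.31 to 0.65 for the same pairs without the interferon lists. Genes are not independent replicates, and dye effects of probes shared by all arrays raise r without any response, so r does not measure a shared response.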

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

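The spike-in test of the SK-MEL-5 array, the count of SK-MEL-5 core genes by size of difference and both tests on RPMI-7951 were chosen only after the result they bear on was seen. A value is listed here because 1 line stood far from the other 3, by Dixon's ratio over the 4 lines at its 95% limit. Chance marks about 1 in 20 sets of values this way, and 14 of 130 named genes and 1 of 21 list medians were marked, with 4 values in RPMI-7951, 3 in A375, 5 in SK-MEL-5 and 3 in SK-MEL-1. Many named genes were chosen for their difference from the other lines, so this share is not a test. The differences between lines were not tested, since no line had a replicate.

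In SK-MEL-5 the median log2 ratio of the core interferon-stimulated genes was 1.16, against 2.50 to 2.75 in the other lines (Dixon ratio 0.841). That median takes all 42 core genes. Of these, 38 were well above background in either channel in SK-MEL-5, 41 in A375 and 42 in RPMI-7951 and SK-MEL-1. Ratios of core genes well above background in neither channel are set by the offset and are not lower bounds. Their part in the low median was not tested. MX1 read 0.91 (others 4.91 to 5.12) and IFI44 0.61 (others 2.85 to 3.09), the latter with untreated signal not well above background in SK-MEL-5, so that 0.61 is a lower bound. Ratios compressed over the whole array are argued against by the spike-in slope of 0.935, within the 0.930 to 0.940 of the other arrays, and by ISG15 at 5.16. Dim signals and the offset stay open: over 22 core genes well above background in both channels on all arrays, the median difference from the mean of the other lines in Agilent's processed ratios was -0.34 (95% interval -1.40 to -0.03), with 9 genes below -1 and 0 above 1. The interval is a spread over genes of 1 array, so it does not measure how much of the difference dim signals and the offset account for. The 9 genes below -1 were well above background in both channels, and Agilent's ratios carry no added offset. Core genes outside these 22 were not part of this test. With normexp and loess, 8 of these 22 genes lay below -1 and 10 within 0.5 of the mean of the other lines. A difference between the lines themselves, which is the difference the design names, stays open and was not tested.

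In RPMI-7951 the chemokine CXCL1 read 4.16 (others 0.12 to 0.67), and beside it the NF-κB list, which did not meet the limit itself, had a median of 1.47 (others 0.14 to 0.45). RNA of other cell types in the treated culture is argued against by the marker list of fibroblast, leukocyte, keratinocyte and endothelial genes, whose median lay at percentile 72.8 of random lists on that array, with 1 of 9 measured markers past 2-fold (KRT14 at 1.06). Wider ratios over the whole array are argued against by the spike-in slope of 0.930, which lay below the 0.932 to 0.940 of the other arrays. A difference between the lines themselves, or in the handling of this single culture, stays open and was not tested. LGALS9 read 2.68 in the same line (others -0.09 to 0.33).

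Across the lines, most genes past the test changed by less than 2-fold, which raises the question of dye effects without swapped dyes. A dye effect of single probes is argued against by a second, non-overlapping probe, whose sign was the same in 82.0% of 111 such rises (95% interval 73.6 to 88.6) and 86.5% of 111 such falls (78.7 to 92.2), against 70.2% and 61.9% for genes not past the test. A trend of the dyes with brightness, left after loess, stays open for the falls, whose median brightness lay at percentile 78.4 of the genes tested (quartiles 62.6 to 91.3; rises 67.3). Turning the sign of arrays can be done in 8 distinct ways, too few for a share under 0.05, and 1 of them, the real one, called as many genes, with 926 called by the real signs and 0 as the highest of the others. A biological explanation, a response to IFN-β, stays open beside the dye trend.

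The remaining values are given without explanation. HLA-DPA1 read -0.13 in SK-MEL-1, where the other lines read 0.55 to 0.57, but its second probe read 0.10 there and 0.15 to 0.56 in the others, so neither the sign nor the distance was repeated. CAPG read 0.73 in A375, where the others read 0.22 to 0.30. CH25H read 1.24 in RPMI-7951, where the others read 0.02 to 0.20, SPP1 read 1.81 in A375, where the others read 0.27 to 0.39, and REC8 read 1.27 in SK-MEL-1, where the others read 0.25 to 0.37, each with untreated signal not well above background in the line named and in at least 1 other, so these comparisons stay open. LUM read -1.19 in SK-MEL-5, where the others read 0.03 to 0.28, with signal well above background on 3 arrays. MMP9 read -1.01 in RPMI-7951, where the others read 0.07 to 0.22, with untreated signal well above background on 3 arrays. IGFBP2 read -1.28 in A375, where the others read from -0.11 to -0.05. SNORD79 read 0.65 in SK-MEL-5, where the others read from -0.53 to -0.36. DDX60L read 1.68 in SK-MEL-1, where the others read 0.24 to 0.45 with untreated signal not well above background, so those are lower bounds and the comparison stays open.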

How the results depend on the processing

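The counts of genes depended on the choice of signals, normalization and lines, while the core interferon list kept a median of 2.07 to 3.37 under every setting run, although its call ended with an estimated correlation, and it was 2.20 to 2.68 when any 1 line was left out. Of 3366 values recomputed under alternatives, 2694 kept their direction and side of the threshold, or a count within 1.5 times. Among 1330 means of named genes, 1092 kept both, 172 kept direction and lost the call, 39 gained one and 27 turned sign. Among 355 list values, 305 kept both, 29 lost and 10 gained a call and 11 turned sign. Leaving out saturated spots changed nothing because no spot was saturated. Signal over background limits dim genes, since the untreated channel was well above background at 36.4 to 47.2% of spots, and there the offset and Agilent's surrogate values set the ratio. No paired analysis was possible because each array already holds the treated and untreated cells of 1 line, so pairing is part of every ratio. Unless said otherwise, the cause was not tested.

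With Agilent's processed signals, 102 genes rose and 2 fell (2 at least 2-fold lower), against 587 and 339 (8). Genes at least 2-fold higher and lower were 1214 and 661 in RPMI-7951, 1643 and 477 in A375, 1135 and 287 in SK-MEL-5, and 727 and 86 in SK-MEL-1, with about 1.1e+02 higher and 3 lower in all lines. The core list's medians were 3.53 in RPMI-7951, 3.89 in A375, 2.11 in SK-MEL-5 and 3.43 in SK-MEL-1, MITF read -0.0061 and LUM 0.018. With the series matrix values, 106 rose and 2 fell (2 at least 2-fold lower). The per-line counts were 1212 and 658 in RPMI-7951, 1639 and 477 in A375, 1133 and 286 in SK-MEL-5, and 724 and 86 in SK-MEL-1, with about 1.1e+02 and 3 in all lines. The core medians were 3.52, 3.89, 2.11 and 3.43, MITF read -0.0058 and LUM 0.019.

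With median centring, the median of all genes moved up by 0.37 and single genes moved by different amounts, since that setting leaves the trend of the dyes with brightness in place. Then 10971 genes rose and 28 fell, 899 and 1 of them by at least 2-fold. The per-line counts were 1436 and 10 in RPMI-7951, 3158 and 7 in A375, 1440 and 0 in SK-MEL-5, and 418 and 1 in SK-MEL-1, with 175 higher and 0 lower in all lines. No list was called lower (0, against 3), and the core median in A375 was 3.64. Of list medians, dedifferentiation turned to 0.27, proliferation to 0.53, cholesterol to 0.43 and reference genes to 0.58. Of named genes, 18 turned sign, and all 18 lay below that setting's median of 0.41: MKI67 at 0.24, MYO5A at 0.055, TGFBI at 0.37, CDH2 at 0.16, MCM6 at 0.038, CENPF at 0.15, BUB1B at 0.19, CYP51A1 at 0.11, SREBF2 at 0.23, SQLE at 0.32, LDHA at 0.23, PDK1 at 0.092, ALDOC at 0.088, EEF1A1 at 0.20, TFRC at 0.14, IPO8 at 0.13, LUM at 0.12 and CD14 at 0.11.

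At an offset of 16, 220 genes fell, 13 by at least 2-fold. Counts at least 2-fold lower were 188 in RPMI-7951, 158 in A375, 80 in SK-MEL-5 and 12 in SK-MEL-1, and 142 genes were higher in SK-MEL-5. Without background subtraction 9 genes were at least 2-fold lower in SK-MEL-1. With the median over a gene's probes 355 rose and 171 fell, 16 named calls ended, MITF read -0.033 and the melanocyte list -0.016. Asking for both channels on all arrays left fewer genes, and the dedifferentiation list read 0.031. A trended and robust prior left 77 rises and 5 falls of at least 2-fold and ended 17 of the 59 named calls. Tested against a 1.5-fold change, 58 rose and 1 fell. With a 1.5-fold threshold, by construction a lower bar, counts were 935 and 642 in RPMI-7951, 871 and 537 in A375, 423 and 386 in SK-MEL-5, 233 and 48 in SK-MEL-1, and 111 and 6 in all lines. With a 3-fold threshold, a higher bar, they were in the same order 144 and 7, 136 and 15, 43 and 0, and 64 and 1. With an estimated correlation camera called 0 lists higher and 0 lower, and the core list at a median of 2.34 had adjusted p = 0.274 (0.00680 by fry). By fry 5 were higher and 0 lower. The mean over glycolysis genes was -0.042.

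With 1 line left out at a time, rises ran from 105 (without A375) to 324 (without SK-MEL-1), and falls from 11 to 238 (the same lines). Changes of at least 2-fold ran from 77 to 129 higher and from 4 to 9 lower. Genes at least 2-fold higher in all remaining lines ran from 57 to 86 (without SK-MEL-5), and lower from 1 to 3. The cholesterol list ran from -0.15 to 0.049 (without RPMI-7951), the melanocyte list from -0.060 (without A375) to 0.096, and the glycolysis list from -0.021 (without SK-MEL-5) to 0.075. ALDOC ran from -0.42 to 0.045 (without RPMI-7951), DCN from -0.016 (without RPMI-7951) to 0.24, MITF from -0.23 (without A375) to 0.35, and LUM from -0.33 to 0.16 (without SK-MEL-5).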

Other observations

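The untreated channels show that the lines differ before treatment, in levels given as log2 relative to the mean of the 4 lines. Melanocyte lineage genes had medians of -1.98 in RPMI-7951, -0.93 in A375, 1.34 in SK-MEL-5 and 1.58 in SK-MEL-1. Among them MITF was at -3.64, -1.97, 2.32 and 3.29 in the same order, and the melanosome antigen MLANA at -4.32, -4.15, 4.89 and 3.58. Dedifferentiation genes ran the other way, with medians of 1.44, 0.33, -1.08 and -0.87, and AXL, a receptor kinase of invasive melanoma, at 2.89, 1.47, -1.76 and -2.60. SOX10, a neural crest factor, was at -3.28 in RPMI-7951 and between 0.75 and 1.48 in the other lines. The signs of MITF, MLANA, SOX10 and AXL were the same with quantile normalization and with scaling to the upper quartile. Each line had 1 untreated channel, so these differences were not tested.

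MHC class II genes had an untreated median of 2.88 in A375 and between -1.24 and -0.93 in the other lines. HLA-DPA1 was at 4.30 and CIITA, the activator of class II transcription, at 2.83 in A375, where alone CIITA was well above background. With IFN-β the class II list had medians of 0.36 in RPMI-7951, 0.43 in A375, 0.30 in SK-MEL-5 and 0.05 in SK-MEL-1, and HLA probes can share signal between genes.

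The tests of the hypotheses that follow were written before their results were seen. The first hypothesis was that core genes with a lower untreated level in SK-MEL-5 than in the other lines respond less there. Across 42 core genes, Spearman's rho was 0.036 (two-sided permutation p = 0.823, 100000 permutations) and Pearson's r 0.10 (permutation p = 0.522), and r was -0.01 without the 2 genes farthest from the median. The relation did not appear, although 30 of the 42 genes had a lower untreated level in SK-MEL-5. With Agilent's processed signals rho was -0.33, and over 22 genes well above background in both channels on all arrays it was -0.38. Genes are not independent replicates, and a ratio shares its untreated signal with the level it is set against, which pushes rho downward.

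The second hypothesis was that the fall of EEF1A1 belongs to a general fall of cytosolic ribosomal protein genes, the other large class of translation genes. Over 80 such genes the medians were -0.11 in RPMI-7951, -0.07 in A375, -0.31 in SK-MEL-5 and -0.016 in SK-MEL-1, at percentiles 0.11, 1.54, 0 and 4.34 of matched random lists. Of these genes 10 fell and 0 rose (camera p = 1.34e-08, p = 0.265 with an estimated correlation). All medians were below 0, the highest at -0.016, as the hypothesis requires, and with Agilent's processed signals they were -0.15, -0.16, -0.27 and -0.08. With median centring they turned to 0.63, 0.90, 0.57 and 0.76, above the medians of all genes in the same lines (0.35, 0.53, 0.37 and 0.44). EEF1A1 went from -0.37, -0.63, -1.08 and -0.45 with loess to 0.37, 0.34, -0.23 and 0.34. Both thus moved up by similar amounts. That setting leaves the trend of the dyes with brightness in place, so it cannot decide on a shared fall. In a comparison made after these values were seen, the ribosomal medians then lay at percentiles 1.4, 10.4, 0 and 65.0 of lists matched for brightness. A shared fall thus depends on the normalization of bright genes and stays open.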
